A study of Mus musculus with 20 samples.

How the data were processed

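Total RNA of CD4+ T cells was sequenced in 20 libraries, 2 for each of 10 groups: WT and KO naive cells, WT and KO Th1 and Th2 cultures, and WT Th1 and Th2 cultures with SGC0649 or SGC0946. The deposited tables hold counts of reads per gene. These counts were made with featureCounts 1.5.3 on Ensembl release 84 of GRCm38 with strand setting 2, per the file headers. Gene lengths stand beside the counts in bases, per the file headers, a deposited unit of its own kind that entered no test. The submitters' processing notes name edgeR and limma, without versions. The aligner was not given in the sources used here. Reads that map to several places were not counted, so genes with near copies (granzymes, the Mcpt family, Gbp2b, Gapdh, Eno1 and the globin genes) are uncertain.

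Protein-coding counts per library ran from 9704500 to 13025588. Per library, 49.5% to 56.3% of alignments were assigned to a gene, 27.4% to 34.9% were multimapping, 8.63% to 15.5% fell outside features and 1.90% to 3.25% were unmapped. Protein-coding genes held 94.8% to 96.3% of assigned counts, and the 10 most abundant genes 3.84% to 8.61%. Between the replicates of a group, the chi-square per degree of freedom against pure counting error was 2.25 to 19.4, so the spread exceeded counting error in all groups. Fold bounds cover counting error only.

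Of 22048 protein-coding genes among 47729 in the table, 13072 passed filterByExpr (at least 10 counts in enough libraries and 15 in total). Symbols carried by several genes were kept apart by identifier (103 entries), and 1 list symbol was in no table. Counts were scaled by TMM (factors 0.878 to 1.08). All 20 libraries were fitted together with 1 mean per group in edgeR 4.0.16 under R 4.3.3 (robust quasi-likelihood fit, 10 residual degrees of freedom, common biological coefficient of variation 0.0963). Each contrast had a quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg over the genes tested, and genes at an adjusted p under 0.05 were called, with no fold threshold. CPM values are TMM-scaled. SE is the standard error of the log2 fold change, taken as its size over the root of the F statistic. Intervals are at 95% and use the same degrees of freedom for all genes, so one that ends near 0 can differ from its test. A gene with 0 counts in a group was given a floor of 3 counts over the group.

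The comparisons were KO against WT in naive cells, Th1 and Th2, SGC0946 against SGC0649 in Th1 and Th2, each compound against none, the culture conditions against each other and against naive cells, and differences between these effects. Comparisons, alternatives and lists were fixed before the data were examined, except where a sentence says otherwise. The named genes were Dot1l, Ifng, Tbx21, Il4, Il13 and Gata3 whatever their result, then the 6 highest and 6 lowest fold changes among called genes with an average log2 CPM of at least 1 and no overlap between the groups, leaving out provisional names, and up to 3 called members of each list. Cd4, Cd5, Thy1 and a list of mast cell and basophil genes were added after values were seen, and a list of pan-T cell genes for the test of dilution. Some genes that the rule named are not reported here.

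Fixed lists covered Th1, Th2, Th17, Treg, Tfh and cytotoxic programs, naive and quiescent genes, activation and checkpoint genes, interferon-stimulated genes, cell cycle, glycolysis, cholesterol, p53 and apoptosis genes, DOT1L partner genes and histone methylation enzymes, and markers of other cell types, handling stress and mitochondria. Lists of at least 3 tested genes were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Signatures of 200 genes came from the contrast of Th1 with Th2 cultures in libraries outside the tested contrast, SGC0649 cultures for the KO and cultures without compound for SGC0946. Alternatives were an estimated correlation, fry (its test of direction), signatures of 50 genes and KO genes past an adjusted p of 0.01. Fry asks whether a list changed and camera whether it changed more than other genes, so their counts of lists answer different questions. For genes they were DESeq2 1.42.0, limma voom, RLE scaling, no filter on low counts (17047 genes), the table that includes genes outside the protein-coding class (15938 genes), the libraries of a contrast alone, the replicate number as a block and each library left out. With 2 libraries per group, no rule for single stray libraries could be applied. Same-numbered libraries deviated together among the WT cultures, where the correlations of deviations were 0.21 to 0.72 over all 15 pairs, and between WT and KO of the same condition, where they were 0.15 to 0.33 over 3 pairs. In these groups the replicate number was taken to pair the libraries, on the data and not on the labels. The main tests did not use this pairing, which entered only as the block among the alternatives. The meaning of the number is not stated. The numbers are those of the sample titles, and the table columns differ for 1 SGC0946 library of each culture condition, which is number 2 by its title and number 1 by its column. Whether the 2 SGC0946 libraries of a condition share a source is therefore open.

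The tests were tried on simulated counts drawn from the means and sizes of these libraries, with 200 genes changed by 1.5-fold, 2-fold or 4-fold. Of the changed genes that were tested, the shares recovered at those sizes were 45.5%, 72.7% and 78.8% with 5.80% false calls over 12969 genes for KO against WT in naive cells, 59.1%, 76.1% and 83.3% with 5.23% false calls over 12964 genes in Th1 and 47.8%, 69.7% and 87.5% with 5.63% false calls over 12979 genes in Th2. For SGC0946 against SGC0649 they were 53.7%, 64.2% and 83.3% with 6.29% false calls over 12984 genes in Th1 and 43.3%, 74.6% and 83.1% with 5% false calls over 12981 genes in Th2. Every recovered gene had the right sign, and of 20 simulated lists per comparison the raised list was called and 0 others. Genes were drawn independently there, so these lists do not test camera calls on lists whose genes move together. The simulated changes were also far fewer than the genes called in the KO comparisons. Each gene was drawn with 1 spread for all groups, as the fit assumes. The real groups differed in spread, with a chi-square per degree of freedom of 2.25 in WT Th1 and 19.4 in WT Th2 with SGC0649. The simulated shares of false calls therefore do not cover contrasts of the noisier groups.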

Results

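RNA-seq libraries were made from CD4+ T cells of mouse spleen and peripheral lymph nodes. The mice carried a CD4-driven Cre recombinase alone (WT) or together with loxP-flanked Dot1l alleles (KO). DOT1L is the histone methyltransferase that places methyl groups on lysine 79 of histone H3. The cells were taken as the naive starting population or after 4 days on plate-bound anti-CD3 and anti-CD28 (1 µg/ml each) under Th1 or Th2 conditions. Th1 cultures received IL-12 and IL-2, each at 10 ng/ml, and an antibody against IL-4 at 10 µg/ml. Th2 cultures received IL-4 and IL-2, each at 10 ng/ml, and an antibody against IFN-γ at 10 µg/ml. Cultured cells were sorted as viable CD4+ cells. WT cultures of both kinds were also grown with 1 µM SGC0946, an inhibitor of DOT1L, or 1 µM SGC0649, its control compound. The 20 libraries form 10 groups with n = 2 each. Counts assigned to protein-coding genes ranged from 9704500 to 13025588 per library. The labels do not say whether the replicates of a group came from separate animals, and the table columns give number 1 to both SGC0946 libraries of each culture condition where the titles give 1 and 2. The p-values therefore measure the spread between these libraries and do not separate technical from biological spread. Each gene's spread was estimated over all 10 groups, so noisier groups borrow from quieter ones. Over well-expressed genes, the SD of the log2 difference between replicates ran from 0.126 in WT Th1 to 0.333 in WT Th2 with SGC0649. It was 0.316 in KO Th2. Log2 changes are given ± SE.

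Dot1l, on chromosome 10 from 80755206 to 80795461 on the plus strand of GRCm38, was measured first. Its RNA stood at 156 ± 14.1 CPM in KO against 167 ± 5.09 CPM in WT (SD, n = 2) before culture (log2 change -0.10 ± 0.11, adjusted p = 0.544), which did not pass the test. It fell in KO Th1 cultures, to 138 ± 10.7 CPM in KO against 181 ± 7.22 CPM in WT (SD, n = 2; log2 change -0.39 ± 0.11, adjusted p = 0.00841), and in KO Th2 cultures, to 103 ± 14.4 CPM in KO against 156 ± 11.024 CPM in WT (SD, n = 2; log2 change -0.60 ± 0.11, adjusted p = 0.000269). The Th1 call was lost without WT Th1 replicate 2 (adjusted p = 0.0612) or KO Th1 replicate 1 (adjusted p = 0.0874). The counts cover every exon of the gene, including those outside the deleted part, so they are a weak check of the genotype labels. With SGC0946 against SGC0649 the differences were -0.03 ± 0.11 on the log2 scale in Th1 and -0.15 ± 0.11 in Th2, and neither passed (adjusted p = 0.962 and 0.486).

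The WT cultures without compound differed in the lineage genes. Ifng, the type 1 cytokine (chromosome 10, 118441047 to 118445892, plus strand), was higher in Th1 than Th2 cultures at 713 ± 18.8 against 23.8 ± 4.29 CPM (SD, n = 2; log2 change 4.91 ± 0.30, adjusted p = 1.24e-08). Tbx21, which encodes the Th1 factor T-bet (chromosome 11, 97098071 to 97115331, minus strand), was likewise higher in Th1 (log2 change 3.93 ± 0.15, adjusted p = 7.52e-12). Higher in Th2 were Il4 (chromosome 11, 53602982 to 53618669, minus strand; log2 change -4.08 ± 0.31, adjusted p = 4.83e-08), its neighbour Il13 (chromosome 11, 53631324 to 53634702, minus strand; log2 change -3.25 ± 0.27, adjusted p = 2.27e-07) and Gata3, the Th2 transcription factor (chromosome 2, 9857078 to 9890034, minus strand; log2 change -3.10 ± 0.15, adjusted p = 5.86e-11). Of the 23 Th1 program genes 20 were higher and 2 lower in Th1 cultures (camera adjusted p = 3.57e-18, estimated-correlation adjusted p = 0.0171). Of the 23 Th2 program genes 20 were lower and 2 higher (camera adjusted p = 3.05e-19, estimated-correlation adjusted p = 0.00143).

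**Figure D1:**
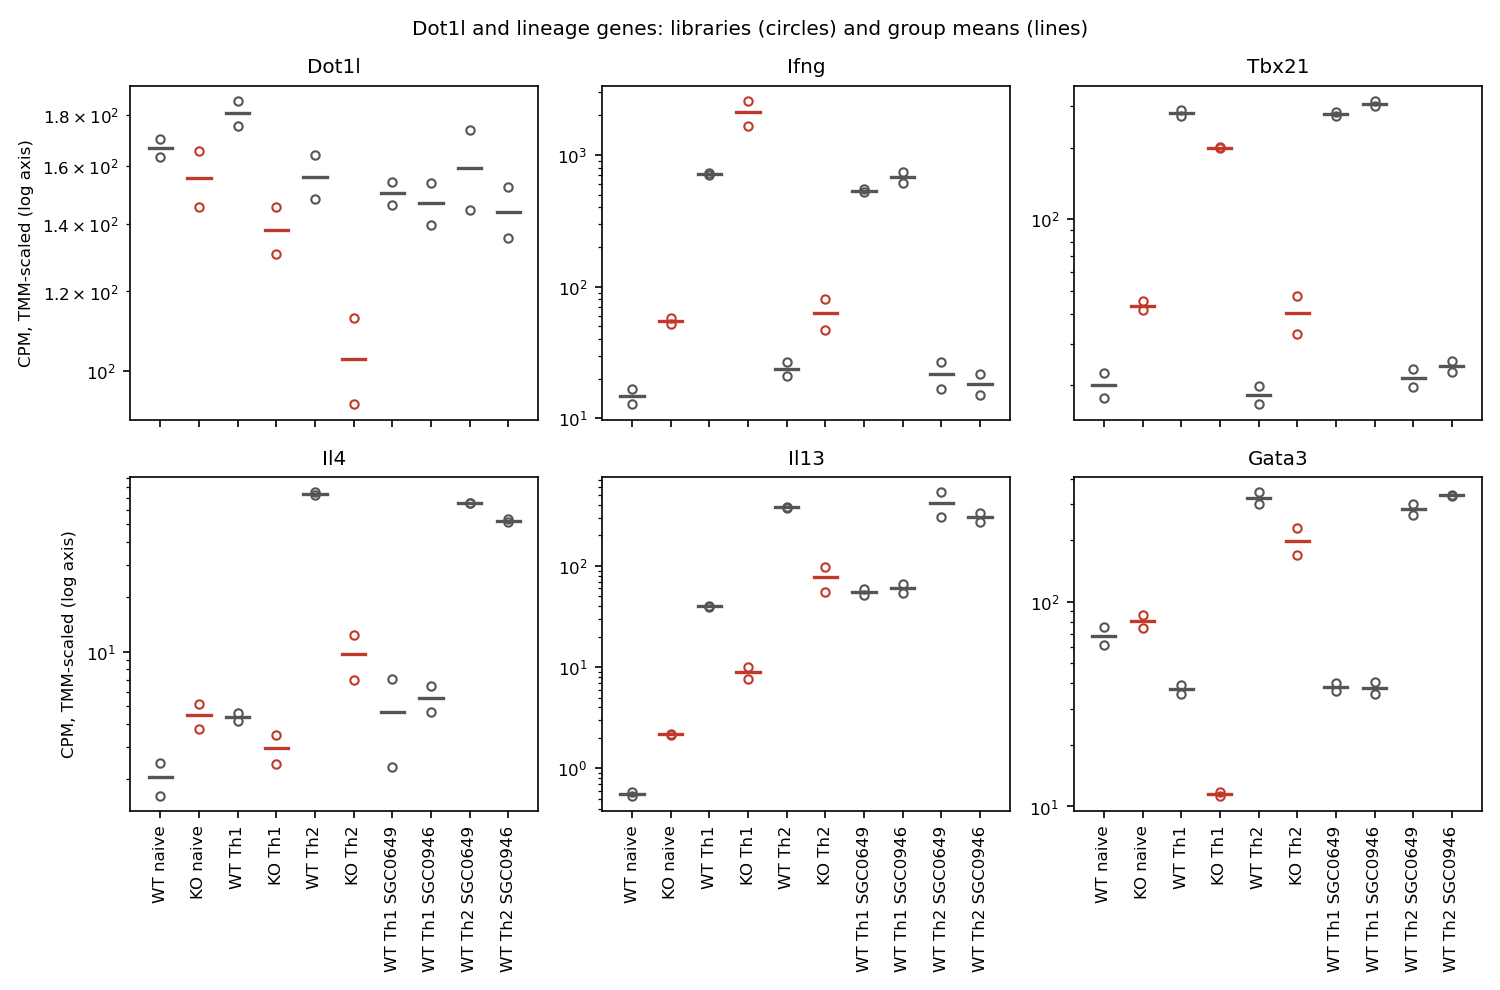
Expression of Dot1l and the 5 lineage genes in each library, in TMM-scaled CPM on a log axis, for the 10 groups on the horizontal axis. Circles are the 2 libraries of a group, lines are group means, and red marks KO. Ifng was 2108 ± 637 CPM in KO Th1 against 713 ± 18.8 CPM in WT Th1 cultures, and Il4 was 9.67 ± 3.77 CPM in KO Th2 against 73.7 ± 1.76 CPM in WT Th2 cultures (SD, n = 2).

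Before any culture, Ifng was 54.6 ± 3.87 CPM in KO against 14.8 ± 2.85 CPM in WT (SD, n = 2), a rise of 1.89 ± 0.30 on the log2 scale (adjusted p = 0.000561). Tbx21 rose with it (43.3 ± 2.68 CPM in KO against 20.1 ± 3.39 CPM in WT (SD, n = 2); log2 change 1.11 ± 0.15, adjusted p = 7.14e-05). Ccr7, the receptor that brings naive T cells into lymph nodes, fell to 402 ± 99.1 CPM in KO against 982 ± 104 CPM in WT (SD, n = 2; log2 change -1.29 ± 0.15, adjusted p = 1.97e-05). Il4, Il13 and Gata3 did not pass the test, with log2 fold changes of 1.14 ± 0.45, 1.93 ± 0.86 and 0.24 ± 0.14 (adjusted p = 0.0732, 0.110 and 0.218). Il4 and Il13 did pass with DESeq2 (adjusted p = 0.0193 and 0.00185) and in a fit of the 4 naive libraries alone (adjusted p = 0.0350 and 0.0103). edgeR's quasi-likelihood test called 3708 of 13072 genes, 2092 higher and 1616 lower in KO. Of these, 1184 were higher and 116 lower by at least 2-fold. The count was 2250 without WT naive replicate 1, 1876 without WT naive replicate 2 and 1567 without KO naive replicate 1.

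Of the 23 Th1 program genes 17 rose in KO naive cells (18 adjusted over the list alone), among them the chemokines Ccl3 (2.32 ± 0.26, adjusted p = 1.52e-05) and Ccl4 (1.92 ± 0.28, adjusted p = 0.000214) and the inhibitory receptor Havcr2 (2.02 ± 0.41, adjusted p = 0.00240; camera adjusted p = 1.19e-14, estimated-correlation adjusted p = 0.0321). Of the 14 naive and quiescent T cell genes 11 fell (11 adjusted over the list alone; camera adjusted p = 1.26e-15, estimated-correlation adjusted p = 0.0227). The largest decreases were those of Dapl1 (log2 change -2.18 ± 0.22, adjusted p = 5.13e-06) and Igfbp4 (log2 change -1.73 ± 0.15, adjusted p = 1.79e-06). These were the lists of this comparison whose camera call held with an estimated correlation. Cytotoxic genes rose in 10 of 18 cases (10 adjusted over the list alone). They included the lectin-like receptor genes Klrg1 (1.996 ± 0.34) and Klrk1 (1.57 ± 0.18; adjusted p = 0.000789 and 2.23e-05; camera adjusted p = 9.65e-07, estimated-correlation adjusted p = 0.233). Interferon-stimulated genes rose in 13 of 22 cases (16 higher and 1 lower adjusted over the list alone), such as Mx1 (2.01 ± 0.16, adjusted p = 7.35e-07), which encodes an antiviral GTPase (camera adjusted p = 2.39e-07, estimated-correlation adjusted p = 0.215).

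The Th2 program had 12 genes higher and 2 lower of 23 (14 and 2 adjusted over the list alone; camera adjusted p = 0.00283, estimated-correlation adjusted p = 0.215). The IL-33 receptor gene Il1rl1 stood at 1.99 ± 0.26 (adjusted p = 0.000104). Of 12 Th17 genes 7 rose (7 adjusted over the list alone; camera adjusted p = 0.00245, estimated-correlation adjusted p = 0.252). Il1r1, which encodes the interleukin-1 receptor, was among them (1.90 ± 0.26, adjusted p = 9.41e-05). Cell cycle genes rose in 9 of 22 cases (12 adjusted over the list alone; camera adjusted p = 0.00127, estimated-correlation adjusted p = 0.559). The mitotic kinase gene Bub1 was one (log2 change 1.38 ± 0.36, adjusted p = 0.0122). Its call was lost without WT naive replicate 1 (adjusted p = 0.0529) or KO naive replicate 1 (adjusted p = 0.102). Cholesterol genes fell in 4 of 21 cases (4 adjusted over the list alone; camera adjusted p = 0.0224, estimated-correlation adjusted p = 0.559). Insig1, which restrains sterol synthesis, was one (-0.499 ± 0.10, adjusted p = 0.00217).

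Other lists without a camera call in the naive comparison also held called genes. The Treg list had 4 genes higher and 4 lower of 13. Lrrc32, which encodes the TGF-β anchor GARP, stood at 20.7 ± 2.14 against 107 ± 12.6 CPM (SD, n = 2; log2 change -2.37 ± 0.23, adjusted p = 7.90e-06). The Tfh list had 4 higher and 1 lower of 10 with Tox2 highest (log2 change 1.64 ± 0.17, adjusted p = 4.63e-06). The activation and checkpoint list had 11 higher and 5 lower of 21. Of 14 p53 and apoptosis genes 2 rose, including the cell cycle inhibitor gene Cdkn1a (log2 change 1.33 ± 0.14, adjusted p = 8.08e-06), and 2 fell, including the survival gene Bcl2 (log2 change -0.88 ± 0.10, adjusted p = 1.32e-05). Glycolysis genes numbered 1 higher and 2 lower of 16. DOT1L partner genes fell in 3 of 11 cases, with Aff4 and Aff1 at -0.45 ± 0.10 and -0.45 ± 0.10 (adjusted p = 0.00362 and 0.00271), and histone methylation enzymes in 3 of 15. Adjusted over the list alone, these numbers were 4 and 4 for Treg, 4 and 1 for Tfh, 12 and 5 for activation, 2 and 2 for p53, 1 and 2 for glycolysis, and 3 lower for both chromatin lists.

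The naming rule took Sprn, Ripk4, Fam171b, Tpbg, Tmem171 and Shisa2 among genes higher in KO naive cells. Sprn had no count in either WT library and 26 counts over the KO libraries, which makes it at least 8.35-fold higher against a floor of 3 counts over the group. Among genes lower in KO it took Gbp2b, Igf2bp3, Arhgap20, Rab6b, Gh and Lrrc32. Gh, the growth hormone gene, fell from 68.3 ± 0.882 to 9.27 ± 0.134 CPM (SD, n = 2; log2 change -2.88 ± 0.14, adjusted p = 1.62e-09). Gbp2b has close paralogs, and its call was lost when 1 library was left out (adjusted p = 0.337 without WT naive replicate 1, 0.187 without KO naive replicate 1, 0.0779 without KO naive replicate 2). So were those of Ripk4 (adjusted p = 0.0518 without WT naive replicate 2, 0.0603 without KO naive replicate 1), Tpbg (0.0919 without WT naive replicate 1, 0.114 without WT naive replicate 2, 0.164 without KO naive replicate 1), Tmem171 (0.156 without WT naive replicate 1, 0.181 without WT naive replicate 2, 0.330 without KO naive replicate 1) and Shisa2 (0.0677 without WT naive replicate 1, 0.0861 without WT naive replicate 2, 0.0840 without KO naive replicate 1). The call of Tmem171 was also lost with the replicate number as a block (adjusted p = 0.0557).

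Markers outside the T cell lists also differed before culture. Myeloid and dendritic cell markers summed to 978 ± 477 CPM in KO against 453 ± 98.3 CPM in WT (SD, n = 2), with 9 of 11 higher (9 adjusted over the list alone; camera adjusted p = 0.0184, estimated-correlation adjusted p = 0.559). Erythroid markers summed to 832 ± 719 against 257 ± 80.2 CPM, with 5 of 7 higher (7 adjusted over the list alone; camera adjusted p = 0.0602). That rise rested on 1 library, with 1340.3 CPM in KO replicate 1 and 323 CPM in KO replicate 2 against 314 and 200.1 CPM in WT. Handling stress genes summed to 6563 ± 233 against 4662 ± 426 CPM, 6 of 10 higher (6 adjusted over the list alone; camera adjusted p = 0.000468, estimated-correlation adjusted p = 0.215). Mitochondrially encoded genes summed to 15083 ± 205 against 18986 ± 1213 CPM, 5 of 7 lower (6 adjusted over the list alone; camera adjusted p = 0.00283, estimated-correlation adjusted p = 0.365). B cell markers were higher in 2 of 10 cases, NK cell markers in 1 of 5 and stromal markers in 1 of 5, each without a camera call. Mast cell and basophil genes, a list added after values were seen, summed to 109 ± 61.0 CPM in KO against 45.5 ± 19.4 CPM in WT (SD, n = 2). Of its 10 tested genes 3 were called higher. CD8 markers summed to 15.8 ± 1.41 against 15.7 ± 0.475 CPM. Of these, Cd8a was not called by edgeR (log2 change 1.58 ± 0.87, adjusted p = 0.194) but passed with DESeq2 (log2 change 1.59, adjusted p = 0.0225). Cd4 itself, chosen after its values were seen, was 403 ± 7.68 CPM in KO against 985 ± 5.77 CPM in WT (SD, n = 2; log2 change -1.29 ± 0.11, adjusted p = 1.29e-06).

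In Th1 cultures the KO cells expressed more Ifng and less Tbx21, the gene of the Th1 transcription factor. Ifng rose to 2108 ± 637 CPM in KO against 713 ± 18.8 CPM in WT (SD, n = 2; log2 change 1.56 ± 0.25, adjusted p = 0.000165). Tbx21 fell to 200.3 ± 0.401 CPM in KO against 279.5 ± 10.9 CPM in WT (SD, n = 2; log2 change -0.48 ± 0.13, adjusted p = 0.00514), a call lost without WT Th1 replicate 1 (adjusted p = 0.0507). The Th2 genes Gata3 (log2 change -1.70 ± 0.16, adjusted p = 4.18e-07) and Il13 (log2 change -2.16 ± 0.31, adjusted p = 6.70e-05) fell, while Il4 was low in both groups, at 2.95 ± 0.755 and 4.36 ± 0.317 CPM, and did not pass (log2 change -0.56 ± 0.40, adjusted p = 0.268). edgeR called 6618 genes, 3248 higher and 3370 lower, of which 1471 and 747 changed by at least 2-fold.

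Of the 14 naive and quiescent T cell genes 13 fell in KO Th1 cultures (13 adjusted over the list alone), the one list here whose camera call held with an estimated correlation (camera adjusted p = 7.35e-21, estimated-correlation adjusted p = 0.0110). The transcription factor genes Bach2, at 17.1 ± 4.22 against 269.6 ± 6.12 CPM (SD, n = 2; log2 change -3.98 ± 0.20, adjusted p = 8.70e-10), and Klf2 (log2 change -3.68 ± 0.27, adjusted p = 1.03e-07) were among them. Pan-T cell genes, a list outside the fixed ones, also fell in 10 of 12 cases, and 1 rose (median -0.77), summing to 4940.0 ± 42.6 CPM in KO against 7509 ± 81.6 CPM in WT (SD, n = 2). Cytotoxic genes rose in 12 of 18 cases and fell in 3 (12 and 3 adjusted over the list alone; camera adjusted p = 2.14e-05, estimated-correlation adjusted p = 0.338). Granzyme gene Gzmc reached 2538 ± 584 CPM in KO against 153 ± 12.6 CPM in WT (SD, n = 2; log2 change 4.05 ± 0.30, adjusted p = 1.49e-07), though reads of the granzyme family can be split between near copies. Summed mast cell and basophil genes moved with this list, at 1594 ± 888 CPM in KO against 169 ± 33.6 CPM in WT (SD, n = 2). The Th1 program split, with 10 genes higher and 9 lower of 23 (10 and 9 adjusted over the list alone; camera adjusted p = 0.538). The chemokine gene Ccl3 (2.57 ± 0.17, adjusted p = 1.53e-08) and the cytokine gene Tnf (1.62 ± 0.13, adjusted p = 4.94e-08) rose, and the chemokine receptor gene Cxcr3 fell (-2.94 ± 0.31, adjusted p = 1.38e-06).

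Tfh genes fell in 7 of 10 cases and rose in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0197, estimated-correlation adjusted p = 0.103). The inhibitory receptor gene Btla was among those that fell (log2 change -2.96 ± 0.13, adjusted p = 6.34e-11). Of 14 p53 and apoptosis genes 10 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 8.50e-05, estimated-correlation adjusted p = 0.103). Those that fell included the pro-apoptotic gene Bcl2l11 (log2 change -1.83 ± 0.24, adjusted p = 2.83e-05) and the anti-apoptotic gene Bcl2 (log2 change -1.68 ± 0.10, adjusted p = 2.13e-09). DOT1L partner genes fell in 6 of 11 cases and rose in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00580, estimated-correlation adjusted p = 0.338). Aff3 stood at 26.2 ± 5.03 against 178 ± 4.84 CPM (SD, n = 2; log2 change -2.77 ± 0.13, adjusted p = 1.02e-10). Interferon-stimulated genes had 9 higher and 5 lower of 22 (10 and 6 adjusted over the list alone; camera adjusted p = 0.0254, estimated-correlation adjusted p = 0.685). Rsad2, which encodes viperin, stood at 2.25 ± 0.26 (adjusted p = 2.86e-06). Glycolysis genes fell in 10 of 16 cases and rose in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.0468, estimated-correlation adjusted p = 0.603). The glucose transporter gene Slc2a3 fell (-1.07 ± 0.15, adjusted p = 2.15e-05).

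The remaining lists had no camera call in Th1. The Th2 program had 5 higher and 10 lower of 23, including Ccr4 (log2 change -3.07 ± 0.19, adjusted p = 3.40e-09), a chemokine receptor of Th2 cells. The Treg list had 5 higher and 7 lower of 13. The Treg factor gene Foxp3 stood at 1.30 ± 0.243 against 24.7 ± 0.276 CPM (SD, n = 2; log2 change -4.23 ± 0.24, adjusted p = 8.70e-10) and Lrrc32 at -5.46 ± 0.31 (adjusted p = 8.40e-09). The Th17 list had 1 higher and 3 lower of 12, activation and checkpoint genes 7 and 7 of 21, cell cycle genes 6 higher of 22, cholesterol genes 8 and 1 of 21, and histone methylation enzymes 2 and 9 of 15. Adjusted over the list alone these were 5 and 10, 5 and 7, 0 and 3, 7 and 9, 2 higher, 8 and 1, and 2 and 9, in the same order. Irf4, an activation-induced transcription factor gene, fell from 781 ± 9.51 to 291 ± 5.88 CPM (SD, n = 2; log2 change -1.42 ± 0.20, adjusted p = 3.55e-05). The demethylase gene Kdm6b fell (log2 change -1.07 ± 0.11, adjusted p = 9.51e-07).

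Mast cell protease genes were 3 of the 6 highest genes in KO Th1 cultures. Mcpt1 was 83.7 ± 43.8 CPM in KO against 1.89 ± 0.212 CPM in WT (SD, n = 2; log2 change 5.46 ± 0.44, adjusted p = 2.56e-07). Its relatives Mcpt2 and Mcpt4 rose too (6.61 ± 0.67 and 5.31 ± 0.56, adjusted p = 1.71e-06 and 1.51e-06), in a family whose members can share reads. Vwf, Olr1 and Layn completed the 6 highest, and BC106179, Dapl1, Izumo1r, Gpr83, Il6ra and Npr3 were the 6 lowest. Izumo1r, which encodes folate receptor 4, fell from 270.0 ± 14.8 to 4.58 ± 2.86 CPM (SD, n = 2; log2 change -5.89 ± 0.23, adjusted p = 1.02e-10), and Il6ra, the interleukin-6 receptor gene, from 64.3 ± 2.90 to 1.39 ± 0.541 CPM (SD, n = 2; log2 change -5.53 ± 0.20, adjusted p = 7.27e-12). BC106179 had no count in KO and 43 counts in WT Th1 libraries, at least 15.2-fold lower against the same floor. Myeloid and dendritic cell markers rose in 4 of 11 cases and NK cell markers in 3 of 5, erythroid markers in 1 of 7, and stromal markers split 2 and 2 of 5. B cell markers fell in 1 of 10 cases, CD8 markers in 1 of 2, and mitochondrial genes split 1 and 4 of 7 and handling stress genes 1 and 3 of 10, with no camera call for any list that was large enough to test. The fall among CD8 markers, that of Cd8b1, was lost without KO Th1 replicate 2 (adjusted p = 0.0563), and Cd8a passed as higher in a fit of the 4 libraries alone (log2 change 0.585, adjusted p = 0.0351). Cd4 stood at 205 ± 8.77 CPM in KO against 1028 ± 30.1 CPM in WT (SD, n = 2; log2 change -2.32 ± 0.12, adjusted p = 3.01e-10), a gene chosen after its values were seen.

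**Figure D2:**
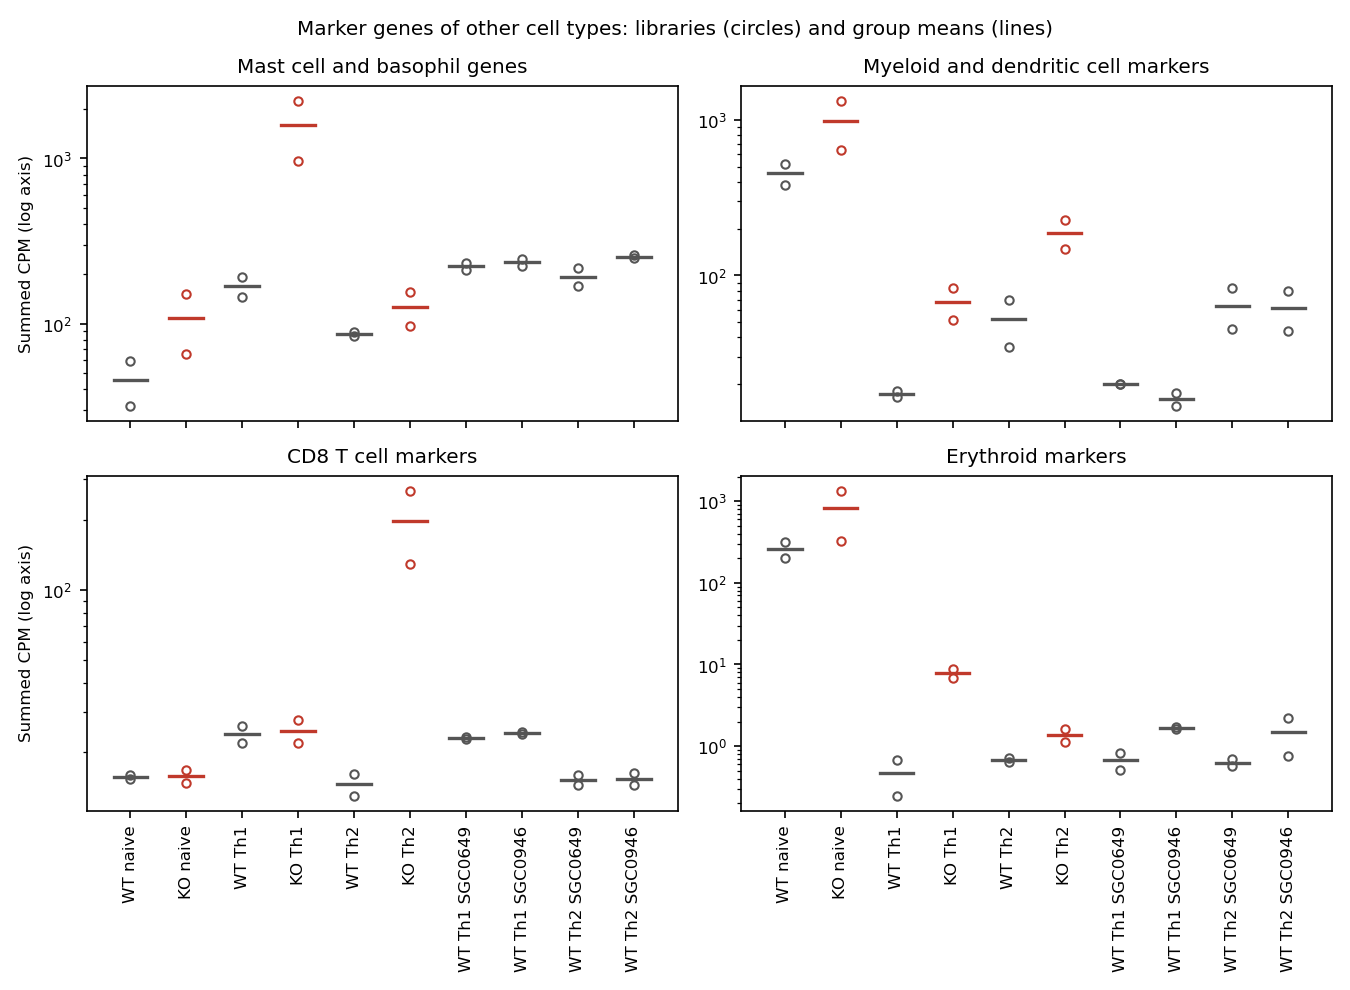
Summed CPM of the marker genes of mast cells and basophils, myeloid and dendritic cells, CD8 T cells and erythroid cells in each library, on log axes, for the 10 groups. Circles are libraries, lines are group means, and red marks KO. The mast cell and basophil sum was 1594 ± 888 CPM in KO Th1, and the CD8 sum was 198 ± 97.4 CPM in KO Th2 cultures (SD, n = 2).

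In Th2 cultures Il4 fell in KO cells to 9.67 ± 3.77 CPM in KO against 73.7 ± 1.76 CPM in WT (SD, n = 2; log2 change -2.91 ± 0.28, adjusted p = 6.71e-07) and Il13 to 77.2 ± 30.1 CPM in KO against 378 ± 8.08 CPM in WT (SD, n = 2; log2 change -2.29 ± 0.26, adjusted p = 4.35e-06), while Gata3 fell by less (log2 change -0.69 ± 0.13, adjusted p = 0.000317). Ifng rose to 63.6 ± 23.6 CPM in KO against 23.8 ± 4.29 CPM in WT (SD, n = 2; log2 change 1.41 ± 0.29, adjusted p = 0.000928) and Tbx21 to 40.2 ± 10.5 CPM in KO against 18.3 ± 2.36 CPM in WT (SD, n = 2; log2 change 1.12 ± 0.16, adjusted p = 1.26e-05). Of all genes, the granzyme genes Gzma and Gzmb gained most CPM, with Gzma at 21248 ± 1428 CPM in KO against 511 ± 27.3 CPM in WT (SD, n = 2; log2 change 5.38 ± 0.31, adjusted p = 5.08e-09). The perforin gene Prf1 was 1593 ± 400.2 CPM in KO against 76.6 ± 14.7 CPM in WT (SD, n = 2; log2 change 4.38 ± 0.19, adjusted p = 8.88e-11). edgeR called 6980 genes, 3465 higher and 3515 lower, of which 1543 and 1152 changed by at least 2-fold.

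Of 18 cytotoxic genes 12 rose and 2 fell in KO Th2 cultures (12 and 2 adjusted over the list alone; camera adjusted p = 4.61e-07, estimated-correlation adjusted p = 0.179). The granzyme gene Gzmb, which also belongs to the Th1 list, reached 19231 ± 3385 CPM in KO against 1506 ± 272 CPM in WT (SD, n = 2; log2 change 3.67 ± 0.16, adjusted p = 2.11e-11), with the caution about near copies given above. CD8 markers moved with this list, summing to 198 ± 97.4 CPM in KO against 14.6 ± 2.25 CPM in WT (SD, n = 2). Both genes were higher, Cd8a at 4.77 ± 0.38 (adjusted p = 1.62e-07) and Cd8b1 at 1.93 ± 0.15 (adjusted p = 1.74e-08). The Th1 program rose in 17 of 23 cases and fell in 3 (17 and 4 adjusted over the list alone; camera adjusted p = 7.00e-06, estimated-correlation adjusted p = 0.179). The interleukin-18 receptor gene Il18rap was higher (log2 change 3.59 ± 0.22, adjusted p = 4.28e-09) and the lymphotoxin gene Lta lower (log2 change -4.66 ± 0.23, adjusted p = 1.06e-10). The Th2 program had 8 genes higher and 11 lower of 23 (8 and 11 adjusted over the list alone; camera adjusted p = 0.130). Il5 fell from 89.4 ± 1.16 to 10.9 ± 3.58 CPM (SD, n = 2; log2 change -3.01 ± 0.22, adjusted p = 1.34e-08). Il9 had no count in KO against 44 in WT libraries, at least 14.9-fold lower.

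The Tfh list fell in 5 of 10 cases and rose in 2 (5 and 2 adjusted over the list alone), and its camera call held with an estimated correlation (camera adjusted p = 0.000288, estimated-correlation adjusted p = 0.0469). Btla dropped to 1.65 ± 0.508 CPM in KO against 207 ± 3.38 CPM in WT (SD, n = 2; log2 change -6.93 ± 0.19, adjusted p = 1.40e-13). Th17 genes fell in 9 of 12 cases and rose in 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00150, estimated-correlation adjusted p = 0.179). The cytokine gene Il21, which the Tfh list shares, fell (log2 change -5.10 ± 0.25, adjusted p = 4.01e-10). Naive and quiescent genes fell in 11 of 14 cases and rose in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 3.58e-08, estimated-correlation adjusted p = 0.104). The transcription factor gene Bach2 stood at -3.53 ± 0.21 (adjusted p = 2.01e-09). Cholesterol genes rose in 18 of 21 cases (18 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.61e-07, estimated-correlation adjusted p = 0.179). Among them were Hmgcs1 and Fdps, which encode synthesis enzymes (1.71 ± 0.11 and 1.79 ± 0.14, adjusted p = 2.63e-09 and 2.33e-08). Cell cycle genes fell in 14 of 22 cases (15 adjusted over the list alone; camera adjusted p = 0.0119, estimated-correlation adjusted p = 0.708). Among them were Bub1 (log2 change -2.08 ± 0.29, adjusted p = 3.04e-05) and the Aurora kinase gene Aurkb (-1.74 ± 0.28, adjusted p = 0.000125).

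Glycolysis genes fell in 9 of 16 cases and rose in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0199, estimated-correlation adjusted p = 0.360). The hexokinase gene Hk2 stood at -1.08 ± 0.18 (adjusted p = 0.000120). The p53 and apoptosis list fell in 9 of 14 cases and rose in 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0203, estimated-correlation adjusted p = 0.231). Zmat3, a p53 target gene, stood at -1.80 ± 0.10 (adjusted p = 5.51e-10). Histone methylation enzymes fell in 9 of 15 cases and rose in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00181, estimated-correlation adjusted p = 0.143). Ezh2, which encodes the H3K27 methyltransferase, went from 215 ± 14.9 to 61.7 ± 10.9 CPM (SD, n = 2; log2 change -1.81 ± 0.11, adjusted p = 1.03e-09). Without a camera call, the Treg list had 8 higher and 2 lower of 13. The ectonucleotidase gene Entpd1 stood at 3.09 ± 0.22 (adjusted p = 2.97e-08) and Foxp3 at -2.59 ± 0.24 (adjusted p = 1.36e-07). Activation genes numbered 10 and 10 of 21, interferon-stimulated genes 11 and 6 of 22, and DOT1L partner genes 4 and 3 of 11. Adjusted over the list alone, these numbers were 8 and 2, 10 and 10, 12 and 6, and 4 and 3. Aff3 fell to 2.90 ± 0.0174 from 40.6 ± 5.36 CPM (SD, n = 2; log2 change -3.80 ± 0.18, adjusted p = 5.45e-11).

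The 6 highest genes of this comparison were Trp73, Fcgr4, Wdr95, Itga1, Fcgr3 and Pdgfrb, and the 6 lowest were Il22, Cxcl10, Btla, BC106179, Cpne6 and Cd200. Fcgr3, which encodes an activating Fc receptor, was 160.4 ± 6.48 CPM in KO against 2.62 ± 0.0939 CPM in WT (SD, n = 2; log2 change 5.93 ± 0.39, adjusted p = 1.60e-08). Itga1, the integrin α1 gene, was 76.7 ± 19.6 CPM in KO against 1.21 ± 0.0384 CPM in WT (SD, n = 2; log2 change 5.97 ± 0.33, adjusted p = 4.65e-10). Cd200 fell to 2.52 ± 0.0980 CPM in KO against 248 ± 10.013 CPM in WT (SD, n = 2; log2 change -6.62 ± 0.20, adjusted p = 3.75e-13). Pdgfrb, a receptor gene on the stromal list, was 68.5 ± 10.4 CPM in KO against 1.12 ± 0.167 CPM in WT (SD, n = 2; log2 change 5.92 ± 0.31, adjusted p = 1.80e-10). That list had 2 of 5 genes higher (camera adjusted p = 0.0252, estimated-correlation adjusted p = 0.179). Myeloid markers had 3 higher and 1 lower of 11 and summed to 188 ± 55.8 against 52.3 ± 24.5 CPM. B cell markers fell in 2 of 10 cases, handling stress genes split 3 and 4 of 10 and mitochondrial genes 1 and 1 of 7, and no NK or erythroid marker was called by edgeR. Cd4 stood at 166 ± 12.3 CPM in KO against 564 ± 29.2 CPM in WT (SD, n = 2; log2 change -1.76 ± 0.12, adjusted p = 2.48e-09) and Cd5, which encodes a surface receptor of T cells, at 15.4 ± 4.18 CPM in KO against 298 ± 0.464 CPM in WT (SD, n = 2; log2 change -4.29 ± 0.15, adjusted p = 1.14e-12), both chosen after their values were seen.

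**Figure D3:**
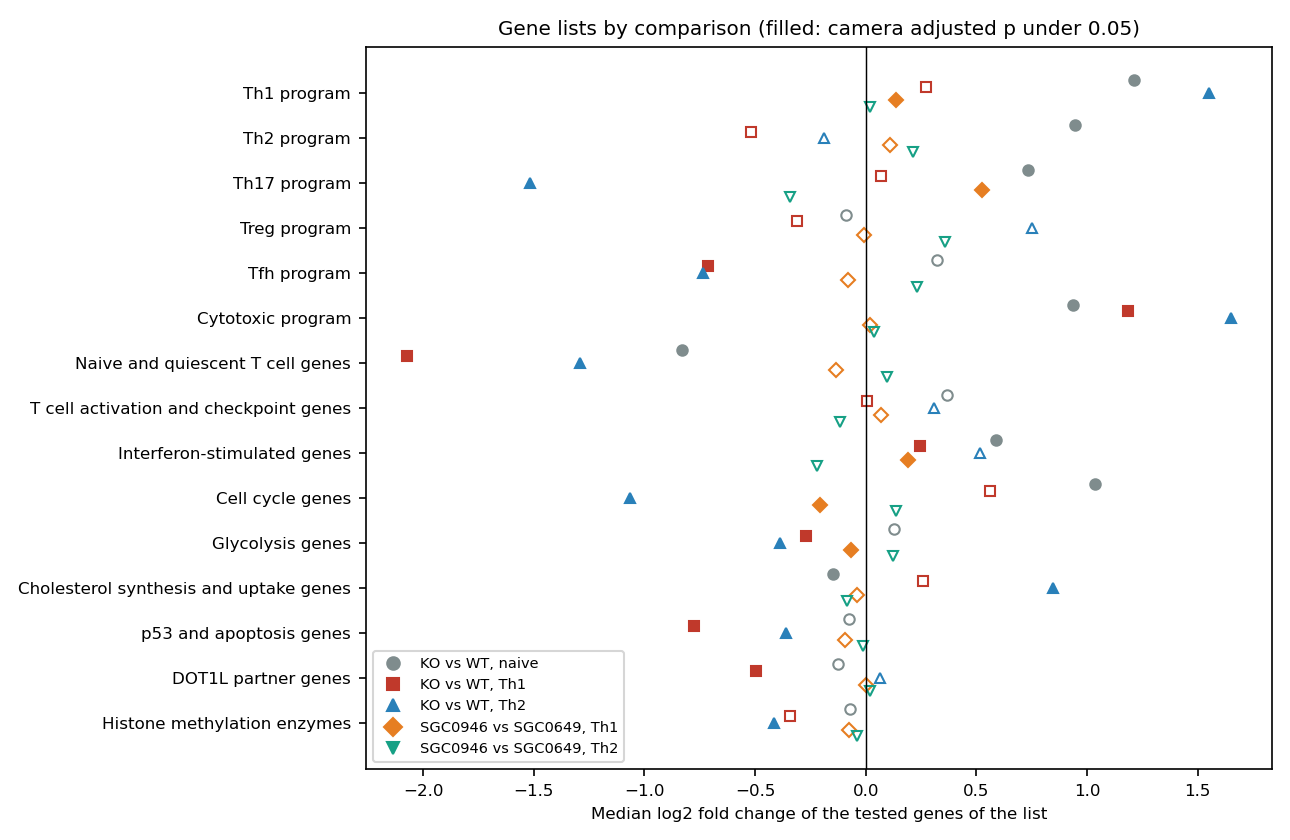
Median log2 fold change of the tested genes of each fixed list (horizontal axis) in the 5 main comparisons. Filled symbols had a camera adjusted p under 0.05 with the preset correlation. The median of the naive and quiescent list was -2.07 in KO Th1 and that of the cytotoxic list was 1.65 in KO Th2 cultures.

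Lineage signatures of 200 genes each, drawn from the SGC0649 cultures and so from libraries outside the KO comparisons, fell in their own culture condition. In KO Th1 cultures 148 of the 200 Th1 signature genes fell and 25 rose (median -0.69 on the log2 scale, camera adjusted p = 8.65e-29, estimated-correlation adjusted p = 0.00982). Pan-T cell genes had a median of -0.77 in the same libraries, with 10 of 12 lower, and mast cell and basophil genes one of 3.42, so a change in the mix of cells is not separated from this fall. In KO Th2 cultures 140 of the Th2 signature genes fell and 38 rose (median -0.90, camera adjusted p = 1.51e-20, estimated-correlation adjusted p = 0.00183). CD8 markers summed to 198 ± 97.4 CPM in these KO libraries against 14.6 ± 2.25 CPM in WT (SD, n = 2). Pan-T cell genes had a median of -0.29 there, with 6 of 12 lower and 4 higher. A change in the mix of cells is not separated from the Th2 fall either. Nor were the signature genes matched to other genes by level. In quartiles of level in SGC0649 cultures of the same condition, the median over all genes was -0.25 in the highest and 0.76 in the lowest for KO Th1. For KO Th2 these medians were -0.11 and 0.30. A trend with level is therefore not separated from the signature results. In each culture condition the signature of the opposite lineage had more genes higher than lower, with 87 and 40 for the Th2 signature in Th1 cultures (camera adjusted p = 0.00205, estimated-correlation adjusted p = 0.197). For the Th1 signature in Th2 cultures they were 108 and 50 (camera adjusted p = 0.000165, estimated-correlation adjusted p = 0.261). The difference between the KO effects in Th1 and in Th2 had a median of -1.10 over the Th1 signature and 0.98 over the Th2 signature, and both calls held with an estimated correlation (p = 0.00402 and 0.000650). In naive KO cells 53 Th2 signature genes rose and 22 fell (camera adjusted p = 0.00929, and adjusted p = 0.469 with an estimated correlation), and the Th1 signature was not called, with 63 and 37 (camera adjusted p = 0.150).

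Across the 3 KO comparisons, which share no library, 596 genes were higher in all and 440 lower in all. Between Th1 and Th2 cultures 1298 genes were higher in both and 1334 lower in both, against 861 and 906 for independent lists of these sizes. Another 586 were higher in Th1 and lower in Th2, and 703 the reverse, so 67.1% of shared calls had the same direction. Between naive cells and Th1 cultures 1030 were higher in both and 816 lower in both (519.8 and 417 for independent lists), 83.3% of shared calls. Between naive cells and Th2 cultures they were 977 and 749 (555 and 435 for independent lists), 74.8% of shared calls. The numbers for independent lists do not allow for a shared source of the libraries, which the labels leave open. Nor do they allow for easier calls among well-expressed genes. Cd5 fell in all 3 (-1.07 ± 0.12, -3.76 ± 0.14 and -4.29 ± 0.15 in naive, Th1 and Th2), as did Cd4 (-1.29 ± 0.11, -2.32 ± 0.12 and -1.76 ± 0.12), while Thy1, a T cell surface gene, rose in all 3 (0.44 ± 0.11, 0.80 ± 0.11 and 1.89 ± 0.11). The adjusted p-values of these 9 results lay between 1.14e-12 and 0.00573, and the 3 genes were chosen after their values were seen. The naive Thy1 call was lost without KO naive replicate 2 (adjusted p = 0.0578).

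SGC0946 and SGC0649 were compared at the same dose and day, so that the test asks what the inhibitor changed beyond its control compound. In Th1 cultures few genes passed. Il17a, the Th17 cytokine gene, was higher at 99.3 ± 4.85 against 38.1 ± 3.60 CPM (SD, n = 2; log2 change 1.38 ± 0.27, adjusted p = 0.0423). Pdpn, which encodes podoplanin, was higher (2.82 ± 0.684 against 0.544 ± 0.377 CPM; log2 change 2.37 ± 0.46, adjusted p = 0.0296), and P2rx3, which encodes an ATP-gated channel, was lower (11.4 ± 0.942 against 24.1 ± 0.987 CPM; log2 change -1.08 ± 0.22, adjusted p = 0.0350). The lineage genes Ifng, Tbx21, Il4, Il13 and Gata3 did not pass, and the 95% interval of the log2 difference was -0.18 to 0.86 for Ifng and -0.32 to 0.31 for Gata3. Ifng did pass in a fit of the 4 libraries alone (log2 change 0.346, adjusted p = 0.0194). edgeR called 61 genes, 53 higher and 8 lower (136 with the replicate number as a block and 192 with that block within genotype), with Emp2, Clec2l, Col5a3, Slc30a2 and Col16a1 the next highest and Samd3, Cdh23, Lrig1, Gfod1 and Ephx1 the next lowest.

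The Th1 count rested on each of the 4 libraries, falling to between 2 and 7 without any one of them. It was 138 with DESeq2, 100 without the filter on low counts and 561 when the 4 libraries were fitted alone. The Il17a, Pdpn and P2rx3 calls were lost without any 1 of the 4 libraries, with adjusted p from 0.183 to 0.426, 0.0778 to 0.433 and 0.162 to 0.421. In all, 6 lists had camera calls with the preset correlation and none with an estimated one. Th17 genes were higher (1 of 12, 7 adjusted over the list alone; camera adjusted p = 1.23e-06, estimated-correlation adjusted p = 0.219), as were the Th1 program (0 of 23 by edgeR, 4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0125, estimated-correlation adjusted p = 0.563) and interferon-stimulated genes (3 of 22 adjusted over the list alone; camera adjusted p = 0.00185, estimated-correlation adjusted p = 0.563). Cell cycle (camera adjusted p = 0.0253, estimated-correlation adjusted p = 0.756), glycolysis (camera adjusted p = 0.0441, estimated-correlation adjusted p = 0.563) and NK cell genes (camera adjusted p = 0.0186, estimated-correlation adjusted p = 0.563) were lower, with no member past edgeR's test.

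In Th2 cultures more genes passed. Lta fell to 13.3 ± 2.16 CPM in SGC0946 against 49.8 ± 7.80 CPM in SGC0649 (SD, n = 2; log2 change -1.90 ± 0.19, adjusted p = 1.86e-05), Tnf to 5.90 ± 0.0184 CPM in SGC0946 against 14.8 ± 0.701 CPM in SGC0649 (SD, n = 2; log2 change -1.32 ± 0.19, adjusted p = 0.000423) and Cd200 to 58.4 ± 5.15 CPM in SGC0946 against 168 ± 13.029 CPM in SGC0649 (SD, n = 2; log2 change -1.52 ± 0.14, adjusted p = 1.65e-05). S1pr1, which encodes the receptor that guides T cells out of lymph nodes, rose (201 ± 9.60 CPM in SGC0946 against 104 ± 16.1 CPM in SGC0649 (SD, n = 2); log2 change 0.95 ± 0.10, adjusted p = 5.13e-05). Il4, Il13, Gata3, Ifng and Tbx21 did not pass, with 95% intervals of the log2 difference of -0.84 to 0.20 for Il4 and -0.92 to 0.42 for Ifng. Il13 did pass without SGC0649 replicate 1 (log2 change -0.813, adjusted p = 0.0298). edgeR called 1040 genes, 712 higher and 328 lower, and 1582 with the replicate number as a block within genotype.

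The count of the Th2 compound comparison depended on the libraries. Fitted alone, its 4 libraries gave 0 calls by edgeR and 1662 genes at an unadjusted p under 0.05. With all libraries in the fit DESeq2 called 1110 and limma voom 1027. The count was 2010 and 448 without SGC0649 replicate 1 or 2, and 321 and 656 without SGC0946 replicate 1 or 2. The Lta, Tnf, Cd200, S1pr1, Btla, Nr4a2, Nr4a3 and Aff3 calls were lost only in the fit of the 4 libraries alone, among the alternatives tried.

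No list had a camera call under SGC0946 in Th2 cultures, where the smallest camera adjusted p was 0.0706, though 1 list was called with the replicate number as a block. Members still changed. Of 23 Th2 program genes 5 rose and 2 fell, of 13 Treg genes 4 rose, and of 21 activation genes 3 rose and 5 fell, including the nuclear receptor genes Nr4a2 and Nr4a3 (-1.22 ± 0.20 and -1.01 ± 0.14, adjusted p = 0.00138 and 0.000403). Adjusted over the list alone, these numbers were 5 and 3, 7 and 1, and 7 and 6. Btla fell (log2 change -1.10 ± 0.12, adjusted p = 4.50e-05), with 1 Tfh gene higher and 2 lower of 10, and Aff3 was the one DOT1L partner gene called (log2 change -1.06 ± 0.13, adjusted p = 0.000192). The Th1 program had 1 higher and 2 lower, Th17 1 and 3, naive and quiescent genes 3 and 2, interferon-stimulated genes 2 and 3, p53 genes 1 and 1, glycolysis 2 higher, cytotoxic 1 higher, stromal markers 1 higher and handling stress genes 1 lower. Glis3, Shisa2, Igsf10, Lcn4, A4galt and Layn were the 6 highest genes, and Timp1, Il1rn, Lad1 and Csf2 stood among the 6 lowest with Lta and Cd200. Of these 12, the calls of Igsf10 (adjusted p = 0.104 without WT Th2 SGC0649 replicate 1, 0.119 without WT Th2 SGC0649 replicate 2, 0.307 without WT Th2 SGC0946 replicate 2), Lcn4 (0.0540 without WT Th2 SGC0649 replicate 1, 0.0905 without WT Th2 SGC0649 replicate 2, 0.241 without WT Th2 SGC0946 replicate 1), A4galt (0.0925 without WT Th2 SGC0649 replicate 1, 0.142 without WT Th2 SGC0649 replicate 2, 0.0802 without WT Th2 SGC0946 replicate 1, 0.133 without WT Th2 SGC0946 replicate 2), Layn (0.0618 without WT Th2 SGC0649 replicate 1, 0.0701 without WT Th2 SGC0649 replicate 2, 0.128 without WT Th2 SGC0946 replicate 2), Il1rn (0.313 without WT Th2 SGC0649 replicate 2, 0.208 without WT Th2 SGC0946 replicate 1), Lad1 (0.0750 without WT Th2 SGC0649 replicate 2, 0.0534 without WT Th2 SGC0946 replicate 1) and Csf2 (0.418 without WT Th2 SGC0649 replicate 2, 0.135 without WT Th2 SGC0946 replicate 1, 0.145 without WT Th2 SGC0946 replicate 2) were lost when 1 library was left out.

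Against no compound, SGC0649 changed 2 genes in Th1 cultures, Gapdh (log2 change 1.56 ± 0.15, adjusted p = 0.000142) and Selenbp1 (log2 change 1.20 ± 0.15, adjusted p = 0.00403; adjusted p = 0.0751 without WT Th1 replicate 1, 0.215 without WT Th1 replicate 2, 0.152 without WT Th1 SGC0649 replicate 1), and 88 in Th2 cultures, 32 higher and 56 lower, again with Gapdh (log2 change 1.502 ± 0.14, adjusted p = 6.87e-05). With the replicate number as a block the Th2 number was 523, and with that block within genotype the numbers were 8 in Th1 and 831 in Th2. Gapdh has many processed pseudogenes, so its count is uncertain. The Th2 number ranged from 2 to 2474 when single libraries were left out, 2474 being without SGC0649 replicate 1. SGC0946 changed 319 and 2478 genes against no compound in Th1 and Th2, with the chemokine gene Xcl1 lower in Th1 (log2 change -1.82 ± 0.32, adjusted p = 0.00860; adjusted p = 0.139 without WT Th1 replicate 2, 0.171 without WT Th1 SGC0946 replicate 1) and Lta (log2 change -2.43 ± 0.18, adjusted p = 7.11e-07) and Cpne6 (log2 change -2.51 ± 0.25, adjusted p = 1.39e-05) lower in Th2. The Th1 number was 591 with the block and 682 with the block within genotype. Leaving out single libraries gave 11 to 104 in Th1 and 886 to 1531 in Th2.

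Genes changed by the deletion were then followed under the inhibitor, in contrasts that share no library. In Th1 cultures 46 genes were higher in both and 7 lower in both, against 13.2 and 2.06 for independent lists, and 98.1% of shared calls had the same direction. In Th2 cultures 521 were higher in both and 241 lower in both, against 189 and 88.2, with 91.3% in the same direction. The limits given above for independent lists apply here too. Lta, Cd200, Btla and Aff3 fell in both Th2 contrasts. As sets, the 3465 KO-higher genes of Th2 moved up with SGC0946 (median 0.19, camera adjusted p = 9.66e-20, and adjusted p = 0.000937 with an estimated correlation). The 3515 KO-lower genes moved down (median -0.09, camera adjusted p = 8.08e-11, and adjusted p = 0.000937 with an estimated correlation). In Th1 the medians were 0.06 and -0.02 (camera adjusted p = 9.66e-06 and 0.00916, and adjusted p = 0.191 and 0.550 with an estimated correlation). Taking only KO genes past an adjusted p of 0.01, the median of the 2260 KO-higher genes in Th1 was 0.12, with 62.6% above 0 (adjusted p = 0.0549 with an estimated correlation and 0.0337 with fry). The median of the 2545 KO-lower genes was -0.02 (adjusted p = 0.554 and 0.634).

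The size of the responses differed. The KO effect differed from the SGC0946 effect for 4012 genes in Th1 and 4179 in Th2 cultures, among them Ifng (1.22 ± 0.35 in Th1 and 1.66 ± 0.43 in Th2, adjusted p = 0.0174 and 0.00901), Gata3 (-1.69 ± 0.22 and -0.92 ± 0.19, adjusted p = 4.06e-05 and 0.00123), and Il4 in Th2 (-2.58 ± 0.37, adjusted p = 0.000116). The Ifng calls were lost when 1 library was left out, in Th1 (adjusted p = 0.0549 without WT Th1 replicate 2, 0.0788 without KO Th1 replicate 1, 0.0695 without WT Th1 SGC0946 replicate 1) and in Th2 (0.0757 without WT Th2 SGC0649 replicate 2). The Th1 number was 2625 without SGC0946 replicate 1, and the Th2 number 2636 in the fit of its own libraries alone. Lineage signatures drawn from the cultures without compound had medians under SGC0946 between 0.04 and 0.11. In Th1 neither signature of 200 genes was called (camera adjusted p = 0.0987 for both), while both were with 50 genes (adjusted p = 0.00790 for both). In Th2 the Th1 and Th2 signatures had camera adjusted p = 0.0121 and 0.00401, and adjusted p = 0.429 for both with an estimated correlation.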

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

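Tests chosen only after the result was seen were those of myeloid cells, of handling stress and of the mast cell and basophil list. The permutation for dilution was also added then. The KO effects differed between conditions by a test of the difference itself, and these differences are given as values. Genes past the threshold numbered 3599 for Th1 against naive, 4668 for Th2 against naive and 6045 for Th1 against Th2. The SGC0946 effect differed between Th1 and Th2 for 68 genes. On the log2 scale, the KO effect in Th1 minus that in naive cells was -1.59 for Tbx21, -4.09 for Il13 and -1.93 for Gata3 (adjusted p = 2.85e-05, 0.00396 and 9.69e-06). In Th2 minus naive it was -0.503 for Dot1l, -4.05 for Il4, -4.21 for Il13 and -0.93 for Gata3 (adjusted p = 0.0206, 3.57e-05, 0.00175 and 0.00125). That call of Dot1l was lost when 1 library was left out (adjusted p = 0.0660 without WT naive replicate 1, 0.0875 without KO naive replicate 2, 0.0864 without WT Th2 replicate 2, 0.131 without KO Th2 replicate 2). In Th1 minus Th2 it was -1.61 for Tbx21, 2.35 for Il4 and -1.01 for Gata3 (adjusted p = 9.30e-06, 0.00152 and 0.000972).

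Of the fixed lists, 5 had a different KO effect in Th1 than in Th2 with the preset correlation. Median log2 differences were -1.32 for the Th1 program (3 higher and 16 lower, camera adjusted p = 0.000232, estimated-correlation adjusted p = 0.5004), 1.31 for Th17 (7 higher and 2 lower, camera adjusted p = 0.00193, estimated-correlation adjusted p = 0.5004) and -0.67 for Treg genes (0 higher and 6 lower, camera adjusted p = 0.00102, estimated-correlation adjusted p = 0.0784). For cell cycle genes the median was 1.499 (16 higher and 0 lower, camera adjusted p = 0.000232, estimated-correlation adjusted p = 0.701), and for cholesterol genes -0.55 (0 higher and 12 lower, camera adjusted p = 0.000891, estimated-correlation adjusted p = 0.626). Genes outside the protein-coding class, among them immunoglobulin and T cell receptor segments, were not used in the comparisons and held a signal as well. Of 2866 tested, 360 were called in naive KO cells, 687 in KO Th1 and 751 in KO Th2 cultures, against 2 and 33 with SGC0946 in Th1 and Th2.

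Mast cell protease genes rose in KO Th1 cultures. Mast cells or basophils stay open although the cultures were sorted as viable CD4+ cells, and all 10 tested genes of their list rose (median 3.42), with the Cpa3 call lost in a fit of the 4 libraries alone (adjusted p = 0.0516). Cpa3 was 829.9% and 970.4% of the Mcpt1 CPM in the KO libraries, but the bound of 10% decides nothing, since the Cpa3 of a WT Th1 library alone would be 49.9%. Myeloid or dendritic cells cannot be told apart from these, because their list had a median of only 0.17 while its summed CPM was higher in both KO libraries than in both WT libraries (67.6 ± 22.7 against 17.3 ± 1.21 CPM, SD, n = 2). Loss of DOT1L activity in the culture also stays open, as Mcpt1, Mcpt2 and Mcpt4 had a mean of 0.36 under SGC0946 in Th1 with an upper 95% bound of 1.14. That bound treats the 3 genes as independent, so it is too narrow if they move together. In KO Th2 cultures Mcpt1 was lower by edgeR (log2 change -1.43 ± 0.39, adjusted p = 0.00728), and Mcpt2 and Mcpt4 were not called. Cpa3 was higher there by edgeR, at 54.2 ± 25.7 CPM in KO against 8.96 ± 2.09 CPM in WT (SD, n = 2; log2 change 2.59 ± 0.64, adjusted p = 0.00400). It was the only 1 of the 10 tested mast cell and basophil genes called higher in KO Th2.

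Before culture, 11 of 14 naive and quiescent T cell genes were lower and 17 of 23 Th1 program genes higher in KO cells. Dilution by cells that are not T cells was tested with 12 pan-T cell genes, whose median was -0.22 with 5 lower and 1 higher. The bound of -0.2 set beforehand was therefore not met. In a permutation added after that value was seen, the mean of the naive list lay 0.5003 below that of the pan-T genes (p = 0.0422). It treated genes as independent and asks only whether the naive list fell further, which dilution behind part of the fall also allows. Dilution therefore stays open for part of the fall. Handling stress, whose genes rose in the same libraries, cannot be told apart from an effect of the deletion, since the lowest sum of these genes in KO was 129% of the highest in WT, and the fall of the naive list in KO Th1 cultures (median -2.07, with a stress list median of 0.08) comes from other preparations. A larger share of effector T cells in KO mice and a change within naive cells both stay open, as does RNA of myeloid cells for part of the higher genes.

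Many genes changed the same way in the KO before culture, in Th1 and in Th2. Strain-derived DNA linked to the Dot1l locus and acting within 10 Mb could not be the general cause, as 1020 of these genes lay elsewhere. Gathering near Dot1l was tested by Fisher's exact test, with an odds ratio of 0.879 (0.491 to 1.47, p = 0.711). Within 10 Mb, 16 of 227 tested genes had changed this way against 1020 of 12844 elsewhere, which argues against such gathering. The test treats neighbouring genes as independent. Single linked genes are not covered by that test. Loss of DOT1L remains as a hypothesis, found and tested on the same data, and differences between the mice other than genotype were not tested.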

How the results depend on the processing

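The tests added after values were seen were the leave-one-out fits of lists, signatures and KO gene sets and the block with the numbers of the table columns. Counts of called genes stayed within 1.5 times under RLE scaling and with the table that includes genes outside the protein-coding class, and the median log2 shift from TMM to RLE lay between -0.0367 and 0.0267. Leaving out single libraries, 1428 gene results kept direction and side of the threshold, 319 lost their call, 1 gained one and 8 uncalled ones changed sign. With 2 libraries per group, a group then rests on 1 library and power falls. Where a value below has no reason beside it, the cause was not tested.

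Without single libraries, KO against WT in naive cells gave 1567 to 3310 genes. SGC0946 against SGC0649 in Th1 gave 100 without the filter, 138 with DESeq2, 561 from its libraries alone and 2 to 7 without single libraries. In Th2 it gave 0 from its libraries alone (1662 at an unadjusted p under 0.05 by edgeR) and 321 to 2010 without single libraries. SGC0649 against no compound in Th1 gave 4 without the filter, 1 with voom, 19 with DESeq2, 190 from its libraries alone and 1 to 2 without single libraries. In Th2 these were 207, 148, 535, 0 (1270 at an unadjusted p under 0.05 by edgeR) and 2 to 2474. SGC0946 against no compound gave 2390 in Th1 from its libraries alone and 11 to 104 in Th1 and 886 to 1531 in Th2 without single libraries. The difference of the SGC0946 effects between Th1 and Th2 gave 140 with DESeq2, 12 from its libraries alone and 9 to 276 without single libraries. The KO effect minus the SGC0946 effect gave 2625 to 3491 in Th1 without single libraries and 2636 in Th2 from its libraries alone.

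Outside the WT cultures and the matched WT and KO groups, the libraries share only a number. Correlations of deviations between same-numbered libraries were -0.13 to 0.09 between WT naive cells and WT cultures, -0.07 to 0.25 within KO and -0.08 to 0.30 between WT and KO of different conditions. Among the WT cultures, the number as a block gave 136 genes for SGC0946 against SGC0649 in Th1, 523 for SGC0649 against none in Th2 and 591 for SGC0946 against none in Th1. With the block within genotype, SGC0946 against SGC0649 gave 192 in Th1 and 1582 in Th2, SGC0649 against none 8 and 831, SGC0946 against none 682 in Th1, and the difference of SGC0946 effects 127. Camera with the block called 1 list with SGC0946 in Th2, and the only named gene whose call the block changed was Tmem171 in KO naive cells. With the numbers of the table columns as the block within genotype, SGC0649 against none gave 4 in Th1 and 311 in Th2. KO against WT gave 4094, 6965 and 7216 genes with the block in naive, Th1 and Th2.

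With an estimated correlation camera called 2, 1 and 1 lists in KO naive cells, Th1 and Th2, and 0 with SGC0946 in Th1. Fry called 14 lists in KO Th1, 0 with SGC0946 in Th1 and 1 in Th2, and single libraries left out gave 0 to 3 lists in the last. The Th1 signature in KO naive cells had adjusted p = 0.0204 without KO naive replicate 1 and 0.0204 to 0.628 over the single libraries left out. The estimated correlation gave 0.469 for the Th2 signature in KO naive cells, 0.197 in KO Th1 and 0.261 for the Th1 signature in KO Th2. Under SGC0946 in Th1, both signatures had 0.00790 with 50 genes. In Th2 the Th1 signature had 0.429 with the estimated correlation, 0.0758 with fry, 0.0553 with 50 genes and 0.000743 to 0.229 without single libraries. The Th2 signature had 0.429, 0.0532 with fry and 6.81e-05 to 0.161 without single libraries. In Th1, KO-higher genes had 0.191 with the estimated correlation and 0.156 with fry, and KO-lower genes 0.550, 0.672 and 8.02e-06 to 0.543 without single libraries.

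All results that changed sign were uncalled differences between SGC0946 and SGC0649. In Th1 the log2 difference of Gata3 became 0.00297 with RLE, 0.000188 without the filter, 0.00147 with all gene classes, 0.00232 with DESeq2 and 0.00163 from the libraries alone. Without SGC0649 Th1 replicate 1 it was 0.0638, and without SGC0946 Th1 replicate 2 0.0870. Dot1l became 0.00449 without SGC0649 replicate 1 and 0.0341 without SGC0946 replicate 1. Il4 became -0.339 without SGC0649 replicate 1 and -0.0240 without SGC0946 replicate 2, and Il13 -0.0431 without the latter. Ifng in Th2 became 0.107 without SGC0649 Th2 replicate 2. Over the single libraries left out, the ranges were -0.104 to 0.0870 for Gata3, -0.103 to 0.0341 for Dot1l, -0.339 to 1.25 for Il4 and -0.0431 to 0.247 for Il13 in Th1, and -0.539 to 0.107 for Ifng in Th2.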

Other observations

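The test of expression level was planned, and its repeats on Th2 levels and under SGC0946 and the medians over all genes were chosen only after the result was seen. Between Th1 and Th2 cultures 6973 genes differed in WT and 7821 in KO. Between KO cultures Ifng was still higher in Th1 (log2 change 5.06 ± 0.30, adjusted p = 6.69e-09), and so was Tbx21 (log2 change 2.32 ± 0.14, adjusted p = 8.48e-10), while Gata3 was lower in Th1 (log2 change -4.11 ± 0.16, adjusted p = 5.58e-12). Against naive WT cells 8791 genes changed in WT Th1 and 9402 in WT Th2 cultures. Outside the protein-coding class, Ighg1 (3.39 ± 0.79 SE, adjusted p = 0.00969) and Igha (3.38 ± 0.76 SE, adjusted p = 0.00899) were among the genes highest in KO naive cells, picked by their values. B cell markers summed to 37.9 ± 19.978 CPM in KO and 18.3 ± 2.94 CPM in WT naive cells (SD, n = 2).

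A hypothesis from the data was that loss of DOT1L raises mainly weakly expressed genes. Genes were divided into quartiles by their level in SGC0649 Th1 cultures, which are in neither arm of the KO comparison. Of called genes, 88.965%, 63.007%, 39.964% and 21.1% were higher in KO Th1 from the lowest to the highest quartile, a difference of 67.9 points. The bound of 20 points set beforehand decides nothing, since contrasts without a deletion passed it too, with 41.3 points (WT Th2 against WT Th1) and 22.1 points (WT naive against WT Th1), so the hypothesis cannot be told apart from a trend with level that needs no deletion. The difference was 53.6 points in KO naive cells and 15.965 in KO Th2 cultures.

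With levels from SGC0649 Th2 cultures instead, the shares higher in KO Th2 cultures were 69.8%, 54.6%, 43.3% and 39.4%. Under SGC0946 they were 90.6%, 68.6%, 55.6% and 67.1% of 1040 called genes in Th2 and 100%, 91.7%, 62.5% and 72.7% of 61 in Th1, on levels from cultures without compound. SGC0649 against none in Th2 had 75%, 47.6%, 38.5% and 24.3%, of only 4, 21, 26 and 37 called genes. On the Th2 levels, WT Th1 against WT Th2 had 42.3%, 54.026%, 53.2% and 44.4% and WT naive against WT Th2 52.3%, 51.6%, 50.8% and 41.031%. Over all genes of the lowest quartile, called or not, the median log2 change was 0.30 in KO Th2 cultures, 0.24 and 0.19 under SGC0946 in Th1 and Th2, 0 for SGC0649 against none, -0.14 for WT Th1 against WT Th2 and 0.03 for WT naive against WT Th2. On the Th1 levels it was 0.76 in KO Th1 cultures, but also 0.52 for WT Th2 against WT Th1 and 0.29 for WT naive against WT Th1, so these medians leave the hypothesis open. RNA of other cell types, which raises genes that T cells express weakly, could account for part of the 67.9 points and was not separated from an effect within T cells. The weakest quartile also carries the largest counting error.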
